A study of Mus musculus with 24 samples.

How the data were processed

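RNA was measured in 24 aortas of mice on the 129S1/SvlmJ background, 4 animals in each of 6 groups. The groups were males and females with intact Bmp2, and males homozygous for a mutated Bmp2 allele named ∆UCS, each either homozygous for the recessive Klotho mutation (Kl/Kl, described in the labels as renal failure) or control (heterozygous or wild type for Klotho, healthy kidneys). Female ∆UCS mice were not analysed here. Per the labels' protocols, aortas were flash frozen after dissection, RNA was extracted with the miRNeasy kit, and directional libraries were made from polyA RNA.

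The deposited table gives TPM, which the authors made in Partek on mm39, per the submitters' processing notes. The aligner, the annotation release, the rule for reads that match several genes and the use of strand in counting are not given in the sources used here. Values of near-identical gene copies, overlapping genes and antisense genes are therefore uncertain. Every deposited TPM column sums to 482073, below the total that TPM has by definition. No value is 0, because a constant was added before scaling. The lowest value of a gene followed the length of its genomic span, introns included (r = 0.995 across 6503 genes, which are not independent replicates), and 98.7% of these values lay within 1% of that length, against 0.6% for the exon length in GENCODE's older mouse annotation. TPM here therefore compares a gene between libraries, but not genes with each other.

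The lowest values stand for 0 reads plus a constant of 0.0001 read, so reads per gene were estimated from them. Of 77251 values between 0.5 and 20 reads for genes with such a floor, 80.9% came out within 0.05 of a whole number, and over all genes 73.1% did. Estimated depth was 20593000 to 61105000 reads in genes per library, and the relative depth ran from 0.619 to 1.52. One TPM of a gene spanning 20 kb stood for 459 to 1130 reads, and of a gene spanning 2 kb for 46 to 113 reads, so a gene of low TPM and short span is measured least precisely. All 24 sample columns were used, leaving 0 unused.

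Genes with a TPM of at least 1 in at least 4 samples were tested (9933 genes), on log2(TPM + 1), with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3. The fit held 6 group means and the library set. The library names number the samples 1 to 12 in 2 sets with different spelling, which is how the set was inferred. All ∆UCS libraries were in set 1, all female libraries in set 2, and the Bmp2+/+ male groups had 2 libraries in each. A fold change on this scale understates the change of low genes. P-values are two-sided, and those called adjusted were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Gene lists (55 lists, 51 with at least 3 tested members) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Genes below the filter were tested one by one with an exact permutation test.

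Named genes were Bmp2 and Kl, and in each comparison up to 8 genes that rose and 8 that fell with the largest fold change among those past the threshold. Such genes had a mean TPM of at least 5 in one group and no overlap between the groups, and predicted genes, pseudogenes and ribosomal protein copies were left out. Up to 5 genes each way were taken for interactions, and up to 4 members of each reported list. Groups, tests, gene lists, this rule and a set of other settings were fixed before the data were examined.

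In 2 libraries the X-linked transcript Xist and the Y-linked gene Ddx3y went against the labelled sex. Groups were kept as labelled in the planned fit. A fit leaving out those 2 libraries was added after the data were seen, with the rule that Xist exceeded Ddx3y in a library labelled male or the reverse in one labelled female. It was run with the deposited scaling, with median-of-ratios scaling, and with limma voom on the estimated reads (22194 genes with at least 10 reads in at least 4 samples, mitochondrial genes and 6 mitochondrial pseudogenes left out). The other settings fixed beforehand were a pseudocount of 0.1, no filter, a TPM of at least 5, median-of-ratios scaling, no library set, age as a covariate, a replicate block, sample quality weights, a fit of the compared groups alone, each library set alone and leaving out each replicate. The quality weights were estimated gene by gene because the REML estimate did not converge, a choice made after the data were seen.

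The procedure was tested on simulated data, with 200 genes changed in the Bmp2+/+ male Kl/Kl libraries, among 9933 genes tested. The changed genes were drawn only from those off the mitochondrial chromosome that reached a minimum mean of estimated reads. Genes with the fewest reads were therefore not among them. Counts were drawn gene by gene from the means and smoothed spreads of the control libraries, at the real depths. The spread of the Kl/Kl libraries, correlation between genes and the 2 libraries against their labelled sex were not simulated. The shares below therefore need not hold for the real data. With all 24 libraries, limma on log2(TPM + 1) recovered 42% of genes changed by 2-fold, 80% of those changed by 4-fold, and 92% of those changed by 8-fold or by 16-fold. With 22 libraries these shares were 32%, 76%, 90% and 88%. In that run 10 of 153 calls were of unchanged genes. Data were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plotted with matplotlib 3.10.9.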

Results

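The study asked how the mouse aorta transcriptome differs with renal failure, with sex and with a changed Bmp2 gene. The design has 6 groups of 4 animals aged 44 to 53 days, each aorta giving 1 library. Estimated depth was 20593000 to 61105000 reads in genes per library. Mitochondrially encoded genes took 40.2% to 61.2% of the TPM total of a library. Because every library has the same total, this share shifts all other genes. Without 2 doubted libraries (below), the median log2 change over all genes was 0.09 in Kl/Kl Bmp2+/+ males, 0.29 in Kl/Kl females and 0.26 in Kl/Kl ∆UCS males. Under median-of-ratios scaling it was −0.02, −0.02 and 0.025 in the same order. The labels describe separate animals, and 0 pairs of libraries held identical values.

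Bmp2 (ENSMUSG00000027358, mm39 chromosome 2, 133394079 to 133404805, plus strand), which encodes a bone morphogenetic protein ligand, had a mean TPM below 1 in every group. It had 72 to 479 estimated reads per library. Its mean TPM as labelled was 0.347 ± 0.101 (SD, n = 4) in Bmp2+/+ control males and 0.317 ± 0.124 (SD, n = 4) in ∆UCS control males, an exact permutation p of 0.714. In Kl/Kl males it was 0.387 ± 0.193 (SD, n = 4) with Bmp2+/+ and 0.562 ± 0.407 (SD, n = 4) with ∆UCS, an exact permutation p of 0.571. The ∆UCS value rested on replicate 2, at 1.17 TPM. A difference in Bmp2 RNA between the Bmp2 genotypes was not detected. Kl (ENSMUSG00000058488, mm39 chromosome 5, 150876072 to 150917282, plus strand), the Klotho gene, had 0 to 30 estimated reads per library. In ∆UCS males its mean was 0.0104 ± 0.00543 TPM (SD, n = 4) in controls and 0.00417 ± 0.00289 (SD, n = 4) in Kl/Kl, an exact permutation p of 0.0857. In Bmp2+/+ males it was 0.00847 ± 0.00351 and 0.00355 ± 0.00456 (SD, n = 4 each, exact permutation p = 0.143) and in females 0.00709 ± 0.00459 and 0.00340 ± 0.00296 (SD, n = 4 each, exact permutation p = 0.257). At this depth Kl does not check the Klotho labels.

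Xist, the X-inactivation transcript, and Ddx3y, a Y-linked helicase gene, matched the labelled sex in 22 of 24 libraries. In matching males Xist was 0.00631 to 0.541 TPM and Ddx3y 2.14 to 5.62 TPM. In matching females Xist was 15.3 to 34.0 TPM and Ddx3y 0.00208 to 0.122 TPM. The library labelled male Bmp2+/+ Kl/Kl replicate 1 had 11.4 TPM of Xist and 0.0138 TPM of Ddx3y. The library labelled female Kl/Kl replicate 2 had 0.0281 TPM of Xist and 4.81 TPM of Ddx3y.

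**Figure D1:**
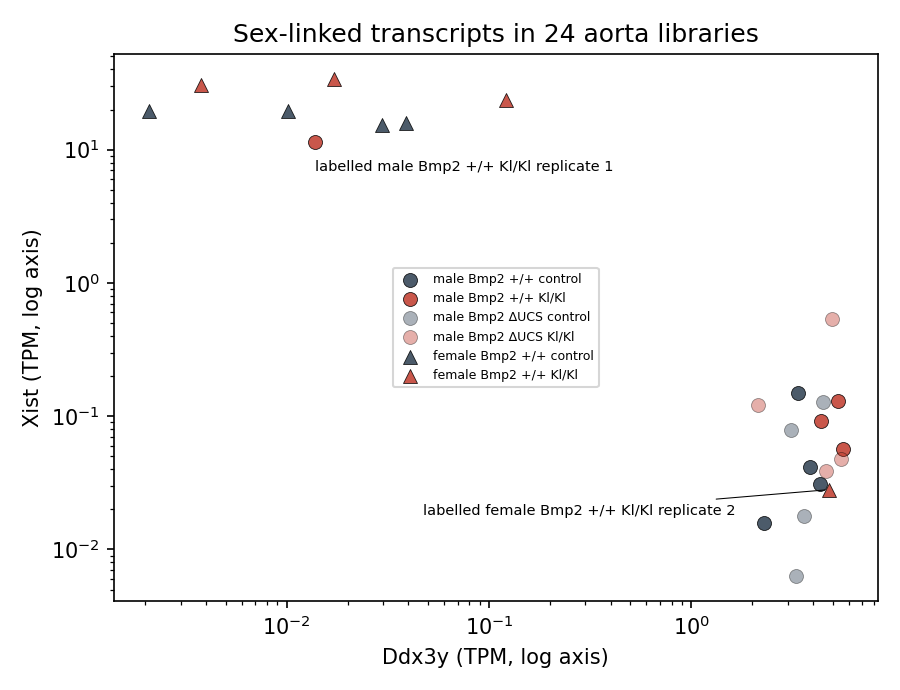
Xist against Ddx3y in TPM on log axes, 1 point per library, with circles for libraries labelled male, triangles for those labelled female, red for Kl/Kl and dark for control, paler for ∆UCS. The library labelled male Kl/Kl replicate 1 lies at 11.4 TPM of Xist, and the library labelled female Kl/Kl replicate 2 lies at 4.81 TPM of Ddx3y.

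With all 24 libraries as labelled, limma called 0 of 9933 genes in each of the 9 comparisons. At an unadjusted p under 0.05 there were 603 genes for Kl/Kl in Bmp2+/+ males, 1498 in females and 1628 in ∆UCS males, 166 for ∆UCS in control males and 89 in Kl/Kl males, 80 for sex in controls and 157 in Kl/Kl, and 166 and 32 for the interactions of Klotho with Bmp2 genotype and with sex. Limma voom on estimated reads also called 0 of 22194 genes in each. Counts of called genes below come from the fit without the 2 libraries, chosen after the data were seen, unless another fit is named. None of its counts above 0 stands in the fit as labelled.

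The first comparison asks how the aorta of male Bmp2+/+ mice differs in renal failure. Spp1, which encodes the secreted phosphoprotein osteopontin, was 153 ± 52.5 TPM (SD, n = 3) in Kl/Kl against 0.403 ± 0.228 (SD, n = 4) in controls, a limma log2 change of 6.71 (SE 0.48, adjusted p = 1.62e-07). Mmp12, the macrophage elastase, rose by 3.91 on the log2 scale (SE 0.28) and Gpnmb, a gene of lipid-laden macrophages and osteoclasts, by 3.74 (SE 0.41). Mpeg1, Cd68 and Lilr4b, all expressed by macrophages, rose by 3.43, 3.36 and 3.29. Hamp2, a hepcidin gene, rose by 3.80 and the immunoglobulin segment Igkv15-103 by 4.04, with 47.9 ± 38.4 TPM (SD, n = 3) in Kl/Kl. Lilr4b and Igkv15-103 belong to families of similar genes, so their values are uncertain. Agpat2, an enzyme of triglyceride synthesis, fell by 2.26 on the log2 scale (limma adjusted p = 0.0413). Under median-of-ratios scaling it fell by 2.40, but its limma adjusted p was 0.0685.

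In all, limma called 103 genes higher and 6 lower in Bmp2+/+ males. Under median-of-ratios scaling these were 148 and 25, and with estimated reads 299 and 32 of 22194 genes. Of the 109 calls, 101 were also called under median-of-ratios scaling. Within library set 1 alone, 2 animals against 2, 13 genes were called, and set 2 then held 1 Kl/Kl library. The count was 36 without Kl/Kl replicate 4, 70 without control replicate 2 and 410 without Kl/Kl replicate 3.

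In females, Spp1 was 245 ± 46.3 TPM (SD, n = 3) in Kl/Kl and 1.81 ± 2.50 (SD, n = 4) in controls, a limma log2 change of 6.78 (SE 0.48, adjusted p = 1.06e-07). Mmp12 rose by 4.67, Mpeg1 by 4.58, Gpnmb by 3.98, Cd68 by 3.97 and Lilr4b by 3.66. Scgb3a1, a secretoglobin of airway epithelium, rose by 3.71 and Reg3g, an antimicrobial lectin of epithelia, by 3.66. With estimated reads the adjusted p of Scgb3a1 was 0.0527. A list of airway epithelium genes, chosen after the data were seen, was also higher in female Kl/Kl libraries, by 1.93 on the log2 scale (exact permutation p = 0.0286). No gene that fell met the rule for naming. Limma called 256 genes higher and 2 lower, a split that became 223 and 153 under median-of-ratios scaling and 484 and 185 with estimated reads. Of the 258 calls, 189 were also called under median-of-ratios scaling. All female libraries were in set 2. The count was 535, 161 and 148 without control replicates 1, 2 and 3, and 134 and 143 without Kl/Kl replicates 1 and 3.

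In ∆UCS males, where neither doubted library belongs, Spp1 was 94.1 ± 53.1 TPM (SD, n = 4) in Kl/Kl and 0.483 ± 0.0977 (SD, n = 4) in controls, a limma log2 change of 5.81 (SE 0.44, adjusted p = 7.92e-07). Scgb3a1 rose by 3.80, Reg3g by 3.54, Mmp12 by 3.02, Cd68 by 2.89, Gpnmb by 2.87, Lgals3, the macrophage lectin galectin-3, by 2.63 and Lyz2, a lysozyme with a close copy, by 2.41. Scd1, a fatty acid desaturase, fell by 3.09, Pygl, the liver glycogen phosphorylase, fell by 1.80, Angptl8, a lipoprotein lipase regulator, fell by 1.63 and S100b, a calcium-binding protein of Schwann cells and adipocytes, fell by 1.18. Limma called 53 genes higher and 11 lower, a split of 71 and 58 under median-of-ratios scaling and of 163 and 86 with estimated reads. With Scd1 and Pygl the adjusted p on estimated reads was 0.0529 and 0.0502. A limma fit of these 8 libraries alone called 46 genes. The count was 40 without control replicate 1 and 40 without control replicate 3, and 41, 38 and 159 without Kl/Kl replicates 2, 3 and 4. The airway epithelium list was 2.37 higher in these Kl/Kl libraries (log2, exact permutation p = 0.0571). This difference rested largely on control replicate 1, at a score of 6.38. The other controls were at 11.95 to 12.67, against 12.26 to 14.01 in Kl/Kl.

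**Figure D2:**
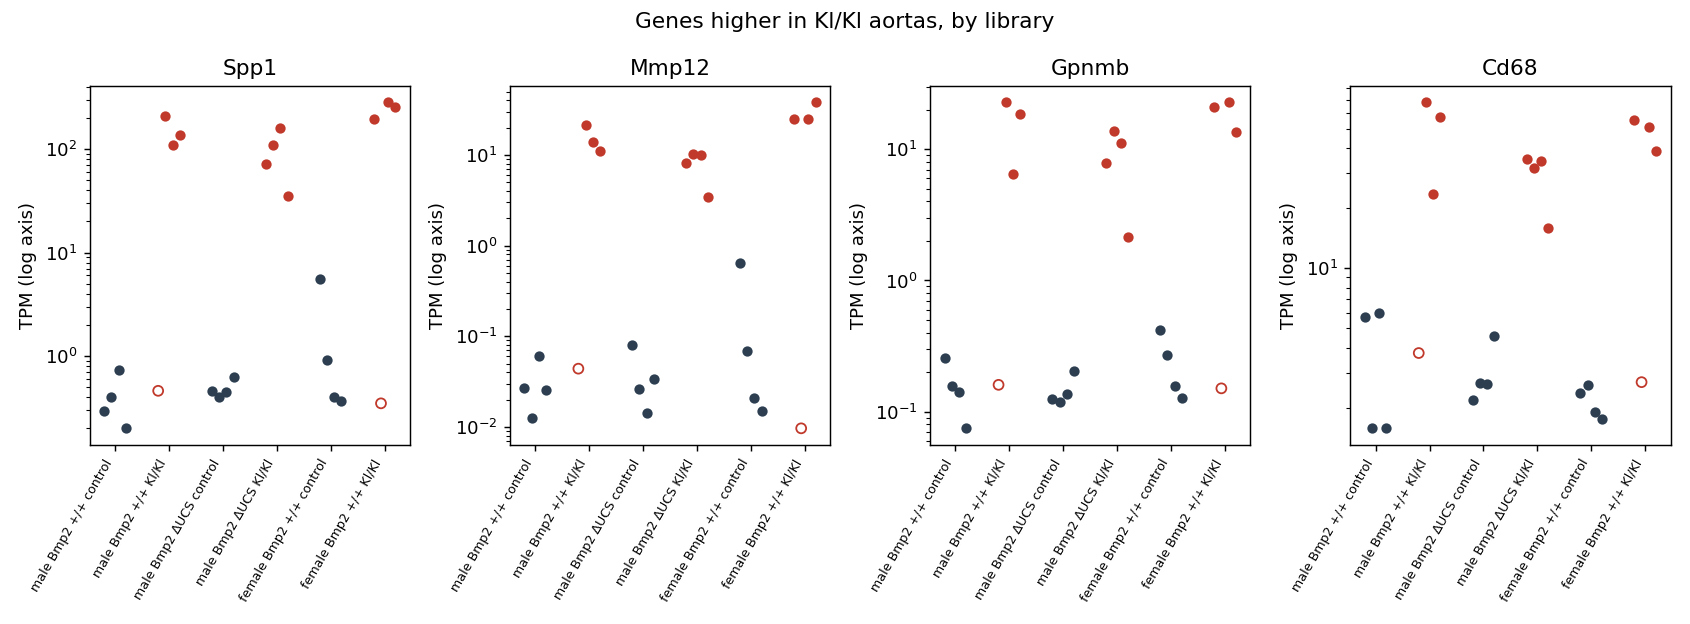
TPM on a log axis of Spp1, Mmp12, Gpnmb and Cd68 in every library by group, filled red for Kl/Kl, filled dark for control, and open for the 2 libraries whose sex-linked genes go against their label. The open points of Spp1 lie at 0.459 and 0.347 TPM, among the controls.

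Across the 3 Klotho comparisons 45 genes were called higher in each, among them Spp1, Mmp12, Gpnmb, Cd68, Ctsk, Mgp, Trem2 and Timp1, and 1 lower. Under median-of-ratios scaling these were 63 and 7, and with estimated reads 135 and 7. Males and females shared 86 of 103 and 256 genes called higher, where independent lists would share 2.65. Bmp2+/+ and ∆UCS males shared 46 where independent lists would share 0.55. These comparisons use different libraries but come from the same fit, with a shared spread for each gene. The expected numbers also treat genes as independent, while genes of a cell type move together. They are therefore no test of the overlap.

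Of 12 tested macrophage genes, 7 rose in Bmp2+/+ males, 9 in females and 7 in ∆UCS males, and 11, 12 and 10 when adjusted over the list alone. Cd14, an endotoxin co-receptor, rose by 2.65, 3.21 and 2.11, and Trem2, a lipid-sensing receptor, by 2.08, 2.13 and 1.47. The camera adjusted p was 4.38e-20, 2.11e-17 and 5.29e-14. With the deposited scaling it was lost (adjusted p = 0.123, 0.103 and 0.12 with an estimated correlation). Under median-of-ratios scaling it held (adjusted p = 0.00532, 0.00442 and 0.0195 with an estimated correlation). Beside these genes, the T and NK cell list had a median log2 change of −0.93 in Bmp2+/+ males, 0.77 in females and 0.94 in ∆UCS males, with 0 of 12 members called by limma, and the B cell list of 0.54, 1.27 and 0.81, with 0 of 11. Of 5 tested neutrophil genes, 0, 2 and 0 rose, and 3, 4 and 4 when adjusted over the list alone, with medians of 1.91, 2.03 and 1.93 (adjusted p = 0.396, 0.58 and 0.635 with an estimated correlation). In females these were Lcn2, an iron-scavenging lipocalin that other cells also make, by 3.22, and Ltf, lactoferrin of neutrophil granules, by 3.15.

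Of 16 matrix proteases and inhibitors, 5, 6 and 4 rose in the same order, and 9, 10 and 4 when adjusted over the list alone. Timp1, a metalloproteinase inhibitor, rose by 2.17, 2.63 and 1.95 and Ctsk, the collagenase cathepsin K, by 3.10, 3.43 and 1.93. The list's camera call was lost (adjusted p = 0.13, 0.252 and 0.673 with an estimated correlation). Of 14 complement genes, 1, 3 and 1 rose, with C3ar1 in each, and 7, 12 and 4 when adjusted over the list alone (adjusted p = 0.52, 0.393 and 0.827 with an estimated correlation). Of 22 genes of endothelial activation and cytokines, 1, 6 and 1 rose, and 5, 10 and 6 when adjusted over the list alone (adjusted p = 0.645, 0.58 and 0.783 with an estimated correlation). The chemokine gene Ccl8 rose by 3.57 in females and by 2.11 in ∆UCS males.

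Of 9 tested osteochondrogenic genes, 2 rose in each comparison, Spp1 and Ctsk, which macrophages and osteoclasts also express. Adjusted over the list alone, 2, 2 and 4 rose (adjusted p = 0.562, 0.734 and 0.673 with an estimated correlation). Below the filter, Runx2, the osteoblast transcription factor, was 0.0149 ± 0.00928 TPM (SD, n = 4) in ∆UCS Kl/Kl and 0.00450 ± 0.00232 (SD, n = 4) in ∆UCS controls, an exact permutation p of 0.0571. In females it was 0.0157 ± 0.0108 (SD, n = 3) and 0.00284 ± 0.000501 (SD, n = 4), an exact permutation p of 0.0286, and in Bmp2+/+ males 0.0124 ± 0.00994 (SD, n = 3) and 0.00563 ± 0.00457 (SD, n = 4), an exact permutation p of 0.314. Runx2 was not among the 135 genes that limma voom on estimated reads called higher in all 3 comparisons. Whether its values follow the cartilage genes that varied between libraries (below) was not tested. Among 7 calcification inhibitors and phosphate genes, Mgp, the matrix Gla protein that inhibits calcification, rose by 2.31, 2.36 and 2.29 on the log2 scale. In Bmp2+/+ males Mgp was 396 ± 217 TPM (SD, n = 3) against 72.8 ± 29.8 (SD, n = 4). Adjusted over the list alone 1, 3 and 2 members rose, and camera did not call this list (adjusted p = 0.113, 0.119 and 0.21).

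Of 12 brown adipocyte genes, 1 fell in Bmp2+/+ males, Otop1, a proton channel gene, by 1.47 on the log2 scale, and 0 were called by limma in females and 0 in ∆UCS males. Under median-of-ratios scaling 1, 2 and 2 fell, with Otop1 in each, at −1.52, −1.49 and −1.33. With the deposited scaling and adjusted over the list alone, 6, 10 and 3 fell. The list's median log2 change was −0.92, −0.79 and −0.61 (adjusted p = 0.13, 0.0606 and 0.0892 with an estimated correlation). Of 21 genes of fatty acid and triglyceride synthesis, 3 fell in ∆UCS males, Acaca, Pnpla3 at −1.44 and Scd1 at −3.09, and adjusted over the list alone 0, 5 and 10 fell. The list's median was −0.47, −0.60 and −0.89 (adjusted p = 0.55, 0.237 and 0.0892 with an estimated correlation). Of 46 nuclear genes of oxidative phosphorylation limma called 0 in any of the 3, with medians of −0.32, −0.23 and −0.13 (adjusted p = 0.254, 0.237 and 0.121 with an estimated correlation). On estimated reads with median-of-ratios scaling, the mean of this list differed by −0.495, −0.697 and −0.529 (log2, exact permutation p = 0.2, 0.0286 and 0.229). Of 22 contractile smooth muscle genes limma also called 0, with medians of 0.19, 0.14 and −0.12, and in females −0.18 under median-of-ratios scaling. Its camera call in ∆UCS males was lost (adjusted p = 0.786 with an estimated correlation).

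Between Bmp2 genotypes, limma called 0 of 9933 genes in control males and 0 in Kl/Kl males, with 216 and 180 at an unadjusted p under 0.05. Limma voom on estimated reads called 0 and 0 of 22194, with 1321 and 627 at an unadjusted p under 0.05. Of 11 BMP target genes limma called 0 in either comparison, with median log2 changes of −0.05 and −0.23, and of 14 BMP ligands, receptors and antagonists 0, with medians of 0.08 and −0.06. In the Klotho comparisons the BMP target Id2 rose by 1.34 in females (limma adjusted p = 0.0183), which under median-of-ratios scaling had an adjusted p of 0.0843. The cardiac ligand gene Bmp10 was called in females at 3.33 (limma adjusted p = 0.0454), but on estimated reads its adjusted p was 0.708. The call rested on 2 of the 3 Kl/Kl libraries, at 60.8 and 24.5 TPM, while the other, at 0.00900 TPM, lay below all 4 controls, which reached at most 0.417 TPM. Nppa, an atrial natriuretic peptide gene, moved beside it, with 3086 and 1478 TPM in those 2 libraries, 160 in the other and 6.03 to 57.8 in the controls. Macrophage genes had a median log2 change of −0.72 in ∆UCS against Bmp2+/+ Kl/Kl males, with 0 of 12 called by limma (adjusted p = 0.608 with an estimated correlation). On estimated reads with median-of-ratios scaling, the mean of this list was 10.49 ± 0.12 (log2, SD, n = 4) in ∆UCS Kl/Kl males. In the Bmp2+/+ Kl/Kl males kept it was 11.04 ± 0.11 (SD, n = 3), without overlap. In controls it was 8.98 ± 0.24 and 8.92 ± 0.52 (SD, n = 4 each). This difference in list means, seen after the fact, was not tested.

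Between females and males, limma called Xist higher and Ddx3y and Eif2s3y lower, in controls and in Kl/Kl alike. Xist differed by 4.08 in controls and 4.74 in Kl/Kl on the log2 scale, Ddx3y by −2.00 and −2.40 and Eif2s3y, a Y-linked translation factor gene, by −2.25 and −2.51. In Kl/Kl this is partly circular, since Xist and Ddx3y decided which libraries were left out. With estimated reads, limma voom called 1 gene higher and 5 lower in controls and 2 higher and 5 lower in Kl/Kl, the additional higher gene being Gp2, a gene named after its values were seen. Of 5 tested genes on the list of X-linked genes with known escape from inactivation, which holds Xist, only Xist was called by limma in these 2 comparisons. The list's camera calls held (adjusted p = 0.00129 and 0.0175 with an estimated correlation). Since Xist is on the list, these calls may rest on it and do not show a difference in the other members.

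For the difference between Klotho effects, limma called 0 of 9933 genes for Bmp2 genotype and 0 for sex, with 205 and 142 at an unadjusted p under 0.05. Limma voom on estimated reads called 0 and 0 of 22194, with 1769 and 600 at an unadjusted p under 0.05. A gene called in only one of the Klotho comparisons is therefore not shown to respond differently by sex or Bmp2 genotype.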

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

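All tests in this part were chosen or written down after the results were seen. Among 150 sets of 4 libraries of 1 group, 23 held a library far from the other 3 by Dixon's ratio, where chance gives about 1 in 20. This excess is not itself evidence, since the genes looked at include Xist and Ddx3y, which defined the 2 doubted libraries, and genes named for not overlapping between groups once these were left out.

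Of these, 15 values came from the 2 libraries whose sex-linked genes went against the label. The library labelled male Bmp2+/+ Kl/Kl replicate 1 had 11.4 TPM of Xist, 0.0138 of Ddx3y, 1.54 of Ctsk, 0.459 of Spp1, 8.55 of Mpeg1 and 38.5 of Agpat2, apart from the other 3 of its group. The library labelled female Kl/Kl replicate 2 had 0.0281 TPM of Xist, 4.81 of Ddx3y, 2.20 of Ctsk, 0.347 of Spp1, 0.00965 of Mmp12, 0.151 of Gpnmb, 2.57 of Mpeg1, 2.69 of Cd68 and 36.6 of Lyz2. A score of 39 genes called between Klotho groups in ∆UCS males alone was 8.46 and 7.98 (log2) in these libraries, 7.76 to 9.05 in the 8 Bmp2+/+ controls and 11.19 to 11.74 in the 6 other Bmp2+/+ Kl/Kl libraries. Exchange with each other would leave both at the Kl/Kl level, against the 8.46 measured, and exchange with a control of this series needs a control at that level, where the highest control was at 9.05. A male Kl/Kl mouse needs Ddx3y near the lowest male value of 2.14, against 0.0138 TPM in the library labelled male Kl/Kl replicate 1. A mixture needs Ddx3y in proportion to its share of male RNA, so a small share is not excluded. The library labelled female was not tested in this way. Libraries of mice other than the labelled ones, without the Kl/Kl response, are consistent with a score of 7.98, and no biological explanation was tested.

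The other distant values were 1.17 TPM of Bmp2 in ∆UCS Kl/Kl replicate 2. Female control replicate 1 had 0.641 of Mmp12, 3.77 of Mpeg1 and 61.9 of Lyz2, above the other controls. ∆UCS Kl/Kl replicate 4 had 6.76 of Mpeg1, 15.9 of Cd68 and 3.56 of Angptl8. ∆UCS control replicate 1 had 2.62 of Scgb3a1.

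For the rise of macrophage genes in Kl/Kl aortas, scaling to a total dominated by mitochondrial genes would end the calls under median-of-ratios scaling, where at least 7 of 12 genes stayed. A lower share of smooth muscle cells would raise endothelial and fibroblast genes as much, but the macrophage list rose above them by at least 1.64 (log2, exact p = 0.0286, the smallest possible), although over Schwann cell genes in ∆UCS males the difference of 1.38 was within the spread (exact p = 0.2). For lymph node or thymus in the dissected tissue, a first test left it open, since the macrophage list exceeded the T and NK list by only 0.26 in ∆UCS males (exact p = 0.943) and the B cell list by 1.04, 0.68 and 0.31 in the 3 comparisons (exact p = 0.457, 0.657 and 0.743). A second test, on the 3 Kl/Kl libraries with a T and NK score below the control median, was void because 2 of them had B cell scores above the control median, but a later one on all 22 libraries argues against it as the whole cause, since with the T and NK and B cell scores as covariates the macrophage score stayed higher by 2.12, 2.38 and 1.43 (95% intervals 1.57 to 2.67, 1.89 to 2.88 and 0.99 to 1.88). A larger number or a changed state of macrophages or of other myeloid cells in the Kl/Kl aorta may be the cause, neutrophils included (their list was 2.60, 2.83 and 1.97 higher, exact p = 0.0571, 0.0286 and 0.0286), as a hypothesis found and tested on the same libraries. Airway tissue in the dissection was not tested as a source. The airway epithelium list differed by −0.20, 1.93 and 2.37 in the same 3 comparisons.

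For lower fatty acid synthesis genes in Kl/Kl aortas, the list's median was −0.58, −0.94 and −1.11 with median-of-ratios scaling alone, in each comparison further from 0 than the −0.47, −0.60 and −0.89 with the deposited scaling, and the list's score with that scaling fell over the 3 comparisons pooled (exact p = 7e-05), which argues against scaling as the whole cause. Less perivascular fat in the dissected tissue would lower Adipoq, the adiponectin gene of fat cells, which limma did not call, at 0.36, 0.12 and −0.26 with the deposited scaling (log2, adjusted p = 0.617, 0.774 and 0.499) and 0.19, −0.37 and −0.61 under median-of-ratios scaling. The common adipocyte list itself fell, by 0.51, 0.78 and 0.87 (log2, exact p = 0.0571, 0.0571 and 0.0286), and by 0.72 over the 3 comparisons pooled (exact p = 9.33e-05). Against this list the synthesis genes fell further in each comparison, but not beyond the spread in any (exact p = 0.171, 0.114 and 0.0857). Pooling the comparisons, a test chosen after those 3, gave a mean difference of −0.68 (exact p = 0.00352), yet the brown adipocyte list fell by 1.31, close to the 1.4 of the synthesis genes, with a difference of −0.09 (exact p = 0.731). Less perivascular fat, in the mouse or in the dissection, and lower synthesis in the fat cells therefore cannot be told apart.

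Other splits of the same libraries test whether chance can be excluded. As labelled, all 9 counts were 0, which every split reaches whatever the data (35 of 35, and 100 of 100 drawn for each interaction), so there was no result to test against chance. The highest other splits called 52, 927 and 1167 genes for the Klotho comparisons, 0 and 3633 for Bmp2 genotype, 0 and 1221 for sex, and 1237 and 1460 for the interactions. For Bmp2 genotype in Kl/Kl, sex in Kl/Kl and the interaction with Bmp2 genotype the second highest called 1575, 796 and 237, which points to a structure of the samples other than the groups, and elsewhere it called at most 2, so that a single split or none stands out. The split with 3633 genes parts the libraries by the TPM share of mitochondrial genes and mitochondrial pseudogenes, 53.64% to 64.57% against 65.68% to 74.47%. That with 1221 genes does so too, 53.96% to 62.78% against 69.98% to 74.9%. Whether this share is the cause was not tested. The split with 52 genes follows the library set, and that with 927 places the library labelled female Kl/Kl replicate 2 among the controls and control replicate 1 among the Kl/Kl libraries. Within set 1 the labelled comparison called 13 genes.

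Without the 2 libraries, 1 of 35 splits, the labelled one, reached the 109 genes in Bmp2+/+ males (highest other 47). This is the smallest share possible. The shares are not adjusted for the number of tests, and the 2 libraries were left out after the data were seen. Such a share therefore does not exclude chance. In females 2 of 35 reached 258 (highest other 267, placing control replicate 1 with the Kl/Kl libraries), and in ∆UCS males 2 of 35 reached 64 (highest other 1084, a single split that exchanges control replicate 4 for Kl/Kl replicate 4), so chance was not excluded. The sides of the split with 1084 also differ in genes at a TPM of at least 1, 5992 to 7293 against 8091 to 10134. Under median-of-ratios scaling the numbers were 1 (173 genes, highest other 80), 2 (376, highest other 721) and 1 (129, highest other 0), and with estimated reads 1 (331, highest other 67), 1 (669, highest other 566) and 1 (249, highest other 0). The labelled split thus had the highest count in each of these but females under median-of-ratios scaling. For sex in controls 1 of 35 reached 3 genes (highest other 0), for genes that include those used to leave libraries out. For sex in Kl/Kl 3 of 10 reached 3 genes (highest other 524), too few splits for a share under 0.05. For Bmp2 genotype in controls and in Kl/Kl the real count was 0, and so it was for both interactions, which every split reaches whatever the data (35 of 35 and 100 of 100), so there was no result to test against chance. The highest other splits of these called 0, 5120, 5618 and 2924 genes, which for all but the first, with 1831, 4633 and 2412 in the second highest, points to a structure of the samples. The split with 5120 genes sets the same libraries apart as that with 3633 genes as labelled.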

How the results depend on the processing

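Alternatives on the 22 libraries, and those using estimated reads, were chosen after seeing the data, and the cause of each change was not tested beyond what fewer genes or libraries make plain. As labelled, every count was 0. Kl/Kl in ∆UCS males became 1 with a pseudocount of 0.1, with a TPM of at least 5, with median-of-ratios scaling and without the library set, and 46 in its own groups alone, and ∆UCS in control males became 1 without a filter. Sample quality weights gave 78, 5354 and 1257 genes for Kl/Kl in Bmp2+/+ males, females and ∆UCS males and 1 for ∆UCS in Kl/Kl males, and sex in controls gave 3 in its own groups alone. Library set 1 alone gave 13 for Kl/Kl in males and 1 for ∆UCS in Kl/Kl males, and set 2 alone gave 1 for Kl/Kl in males and 1 for sex in Kl/Kl. Leaving out 1 replicate gave 0 to 9 for Kl/Kl in males (9 without the library labelled Kl/Kl replicate 1), 0 to 241 in females (241 without the library labelled Kl/Kl replicate 2) and 0 to 1 for sex in Kl/Kl.

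Leaving out the 2 libraries gave 109, 258 and 64 for the Klotho comparisons, and 3 and 3 for sex. With median-of-ratios scaling these were 173, 376, 129, 4 and 4, and with estimated reads 331, 669, 249, 6 and 7. In the same 22 libraries no filter gave 988 for Kl/Kl in females and 5 for sex in controls. A TPM of at least 5 gave 48, 129 and 320 for the Klotho comparisons, no library set 99 in ∆UCS males, quality weights 263, 6373 and 1392 and 1 for the interaction with sex. Own groups alone gave 15 in males, 620 in females and 0 for sex in Kl/Kl. Set 1 alone gave 13 for Kl/Kl in males and 1 for ∆UCS in Kl/Kl males, and set 2 alone 8 for sex in Kl/Kl. Leaving out 1 more replicate gave 36 to 410, 134 to 535 and 38 to 159 for the Klotho comparisons, 2 to 8 for sex in Kl/Kl and 0 to 1 for the interaction with sex.

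Of 459 list tests as labelled, 161 passed, against 0 with an estimated correlation and 0 with fry. Without the 2 libraries 2 passed with an estimated correlation and 22 with fry, and with estimated reads 9 with an estimated correlation. Of 569 alternative fits of 29 named gene results, 462 kept their direction and side of the threshold, 107 no longer passed it and 0 reversed. These genes were named for passing the threshold in the same libraries without overlap between groups. The lack of reversals is therefore largely fixed by that choice and is no support of its own. The replicate numbers do not pair the samples: of 60 same-number pairs, 29 correlated above 0.1 in their deviations (mean r = 0.039), and 6 of 24 libraries correlated best with their own number. With a replicate block the counts stayed 0 as labelled and were 95, 184 and 50 for the Klotho comparisons without the 2 libraries. Control and Kl/Kl libraries of Bmp2+/+ mice also lie side by side by index number, 6 of 8 such pairs with the same age. In several pairs the library names carry consecutive numbers, but the labels do not say what the pairs share. Of the 8 pairs 4 correlated above 0.1 (−0.18 to 0.486), and without the 2 libraries 3 of 6 (−0.211 to 0.274). So few pairs cannot show whether the samples are paired. With such an index pair block, chosen after seeing the data, the counts stayed 0 as labelled. Without the 2 libraries the block lowered them from 109 to 57 in males and from 258 to 150 in females. Depth limits low genes such as Kl, with 0 to 30 estimated reads.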

Other observations

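The added lists of this part were chosen after the values were seen. Markers of tissues beside the aorta varied between libraries of the same group. The score of 8 stratified epithelium genes of the oesophagus ran from 3.08 to 15.48 (log2), that of 8 airway epithelium genes from 6.38 to 14.21 and that of 6 cartilage genes from 3.39 to 9.49. Krt13, a keratin of stratified epithelium, was 0.470 to 685 TPM among the ∆UCS controls and 15.9 to 1891 TPM among the Bmp2+/+ control males. Nppa, an atrial natriuretic peptide gene, was 160 to 3086 TPM among the 3 female Kl/Kl libraries kept and 6.03 to 57.8 TPM among female controls, the comparison in which limma called Bmp10. In ∆UCS males the airway list was 2.37 higher in Kl/Kl (log2, exact permutation p = 0.0571), and in females 1.93 higher (exact permutation p = 0.0286), the comparisons in which Scgb3a1 and Reg3g rose. The ∆UCS difference rested largely on control replicate 1, the library with the score of 6.38. In Bmp2+/+ males the airway list's difference of −0.20 was within the spread between libraries. In ∆UCS males the stratified epithelium list was 4.81 higher in Kl/Kl (exact permutation p = 0.0571), and in females the difference was −4.03 (exact permutation p = 0.0857).

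Below the filter, Ibsp, the bone sialoprotein gene, was 0.373 ± 0.175 TPM (SD, n = 4) in ∆UCS Kl/Kl and 0.0297 ± 0.0252 (SD, n = 4) in ∆UCS controls, an exact permutation p of 0.0286, the smallest possible. Without the 2 doubted libraries it was 0.470 ± 0.478 (SD, n = 3) in Bmp2+/+ Kl/Kl males and 0.00697 ± 0.00477 (SD, n = 4) in their controls, and 0.628 ± 0.403 (SD, n = 3) in Kl/Kl females and 0.0187 ± 0.0110 (SD, n = 4) in theirs, with the same p in each. Limma voom on estimated reads called Ibsp higher in all 3 comparisons, by 5.38 in Bmp2+/+ males, 4.55 in females and 3.54 in ∆UCS males (adjusted p = 0.00273, 0.00318 and 0.0118). Alpl, the alkaline phosphatase gene, was 0.130 ± 0.0117 (SD, n = 4) and 0.168 ± 0.0560 (SD, n = 4), an exact permutation p of 0.286, and in Bmp2+/+ males and females that p was 0.914 and 0.657. Vdr, the vitamin D receptor gene, was 0.113 ± 0.0675 (SD, n = 4) and 0.0231 ± 0.0105 (SD, n = 4), an exact permutation p of 0.0857. In females Vdr was 0.130 ± 0.0953 (SD, n = 3) in Kl/Kl and 0.0338 ± 0.00992 (SD, n = 4) in controls (exact permutation p = 0.0571), and in Bmp2+/+ males 0.0805 ± 0.0525 (SD, n = 3) and 0.0590 ± 0.0274 (SD, n = 4) (exact permutation p = 0.514). The ∆UCS controls were themselves below the Bmp2+/+ control males in Vdr (exact permutation p = 0.0286). The permutation p-values are not adjusted for the number of genes looked at.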
